A study of Mus musculus with 6 samples.

How the data were processed

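The series holds 6 arrays of total RNA from lumbar spinal cord of E15.5 mouse embryos, 3 from Tnc wild type and 3 from Tnc knockout. Per the labels' protocols, RNA was extracted with RNeasy columns, amplified and biotin-labelled with whole-transcript kits, and hybridised to an Affymetrix array whose annotation is that of Mouse Gene 1.0 ST. The deposited values are on the log2 scale, made by the authors with RMA per the submitters' processing notes, with no version given. RMA corrects background, equalises the distribution of probe signals between arrays and summarises the probes of each transcript cluster, which compresses small differences and removes any global shift. The deposited table holds 35557 transcript clusters. Scan dates, array batches and the litters of the embryos are not given in the sources used here. The labels call the samples biological replicates, and the number of arrays limits the precision of every value.

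Array platform annotation paired 21789 clusters with exactly 1 gene symbol and 1621 with several, and 12147 were not listed in it. Genes were named only from the first kind. Symbols were updated through entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, where 19856 of the 19938 resulting genes matched. No genome build is named for the values, so that table served for names, chromosomes and gene order only, and no coordinates are given. For the 999 genes with more than 1 cluster, the cluster with the highest mean over the 6 arrays stood for the gene. No filter on dim genes was applied, and 1194 olfactory and vomeronasal receptor genes, with a 95th percentile of 6.13, served as a guide to background.

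Knockout and wild type were compared gene by gene with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the log2 values of all 6 arrays with group as the only term. P values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Tnc was also compared by an exact permutation test. Gene lists were compared by limma's camera with a preset correlation between genes of 0.01, adjusted over 34 lists, beside camera with the correlation estimated per list, camera on ranks, and fry. Of 35 lists fixed by name, with 593 of 651 listed symbols measured, 1 had fewer than 3 measured genes and was not tested. The lists covered patterning factors, ventral astrocyte position, radial glia, astrocytes, oligodendrocytes, neurons, motor neurons, interneurons, 7 signalling groups, 4 matrix groups, 2 cell cycle phases, 9 other cell types, Hox genes, stress genes, mitochondrial genes, sex-linked genes and chromosome 4 neighbours of Tnc. Tnc itself was in none. Lists share genes, so their tests are not independent.

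Genes named are Tnc, the 10 higher and 10 lower genes of smallest p among those whose groups do not overlap (the rule's fallback, since none passed), 14 genes fixed by name, and, per list, up to 4 members that pass over the list alone or else the 2 of smallest p. Other list members, the 5 genes with a change of 1 log2 unit or more and the genes of single arrays were named after their values were seen. The tests were checked on simulated data with the array number, levels and spread of the real ones, but with noise independent between genes. The list test called 0 of 34 lists when nothing was changed. This cannot show how the preset correlation serves genes that vary together. In the real arrays the correlation estimated for the endothelium list was 0.499. It was 0.465 for motor neurons, 0.181 for neurons, 0.159 for ventral astrocyte position and 0.139 for meninges. For the astrocyte and oligodendrocyte lists it was 0.005 and -0.046, below the preset. These 2 lists did not pass with it either, so a larger correlation does not account for their loss. Alternatives chosen before the data were examined were leaving out each array, the replicate number as a block, 2 filters on dim genes, an intensity trend with and without robust fitting, array weights, renewed quantile normalization, median centring, 2 other rules for several clusters of a gene, all clusters of the table, other thresholds and the other list tests. A sex term, cyclic loess and the removal of 2 wild-type arrays were added after seeing the data. The sex term leaves knockout replicate 2 alone against the wild-type arrays, so values with it rest on 1 knockout array. Figures were drawn with matplotlib.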

Results

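Gene expression was measured in lumbar spinal cord dissected from E15.5 mouse embryos. The 6 samples were 3 wild-type and 3 knockout for Tnc, the gene for tenascin-C, a large extracellular matrix glycoprotein made by radial glia and early astrocytes of the embryonic spinal cord. Each sample was hybridised to 1 whole-transcript oligonucleotide array, and the labels call the 3 samples of each group biological replicates of strain SV129. The deposited log2 values covered 35557 transcript clusters, and their medians per array lay between 6.96 and 7.10. A single clear gene symbol was paired with 21789 of these clusters, which gave 19938 genes for testing. The number of arrays limits the precision of every value, and no sequencing depth applies.

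The comparison asks what loss of tenascin-C does to gene expression in the cord at the stage when astrocytes are specified, with patterning genes as the theme that the series title names. In the knockout arrays Tnc itself stood lower, and the radial glial genes Fabp7, Sox9, Nfia and Slc1a3 stood level. The ventral patterning factors Nkx2-2 and Olig2 stood slightly higher, and patterning factors did not pass as a list. The ventral factors Nkx2-9 (0.05) and Nkx6-2 (-0.03) differed little over all 6 arrays, but both changed sign with some single array left out. No gene with a single symbol passed the test over all genes. Among gene groups, those of endothelium, oligodendrocyte lineage, astrocytes, ventral astrocyte position, neurons and motor neurons rose as sets and meningeal genes fell as a set, under a test that presets the correlation between genes. None of these 7 sets passed when that correlation was estimated from the arrays. For the astrocyte and oligodendrocyte sets the estimate was below the preset, so a larger correlation does not account for their loss. Of the 27 other lists tested, 22 had a median that changed sign when some single array was left out, so their directions are not settled. Of the 94 genes other than Tnc that the naming rule gave, 49 moved by over 1.5 times or changed sign with some single array left out, 10 of them changing sign, and the values of such genes describe these 6 arrays only.

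The level of Tnc was 10.32 ± 0.36 in wild type (SD, n = 3) and 9.62 ± 0.15 in knockout (SD, n = 3). The log2 difference was -0.69, with a standard error of 0.17 and a 95% confidence interval from -1.09 to -0.30, so that the knockout signal was 61.8% of the wild-type signal. The 3 knockout arrays read 9.64, 9.76 and 9.47, all below the lowest wild-type array at 10.02. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 arrays against 3 allow. In limma the unadjusted p was 0.00380 and the adjusted p over all genes was 1. Which part of the gene was removed, and which part the single Tnc transcript cluster covers, are not given in the sources used here, so the remaining signal does not measure intact transcript.

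**Figure D1:**
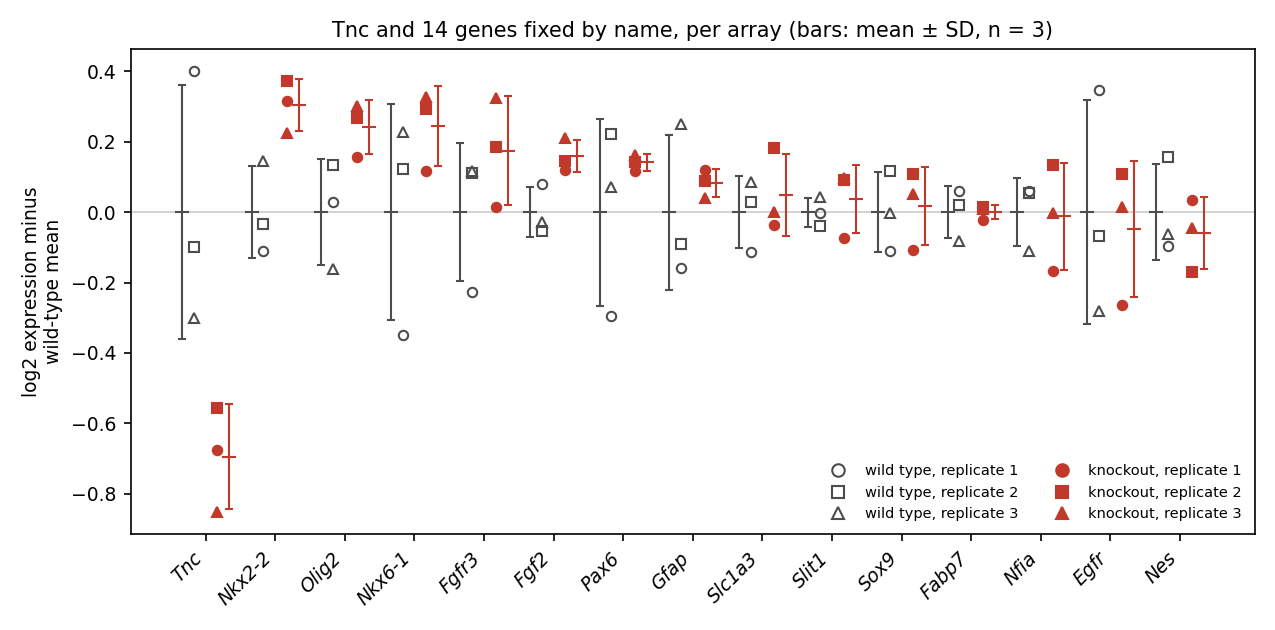
Log2 expression of Tnc and 14 genes chosen by name, as the difference from each gene's wild-type mean (vertical axis, log2 units), for each of the 3 wild-type arrays (open grey) and 3 knockout arrays (filled red), with bars for mean ± SD. All 3 knockout arrays lie below all 3 wild-type arrays for Tnc and above them for Nkx2-2, Olig2 and Fgf2, while for the 11 other genes the groups overlap.

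Across the transcriptome, limma with Benjamini-Hochberg adjustment found 0 of 19938 genes past an adjusted p of 0.05, and the smallest adjusted p was 1 after rounding. An unadjusted p under 0.05 was reached by 339 genes, 186 higher and 153 lower in knockout. That is 1.70% of genes where chance alone gives 5%. An unadjusted p under 0.01 was reached by 43 genes, 23 higher and 20 lower, against 199 by chance. That count ran from 23 (without wild-type replicate 2) to 104 and 247 (without wild-type replicates 1 and 3) when 1 array was left out, and was 31, 34 and 36 without knockout replicates 1, 2 and 3. The 3 knockout values lay wholly above or below the 3 wild-type values for 1161 genes, or 5.82%, where chance gives 10%. The median size of the log2 change was 0.05, against a median within-group standard deviation of 0.12. On simulated data of the same size the test recovered 46.3% of genes changed by 0.5 log2 units and 82.1% of those changed by 1. The simulated noise was independent between genes, and some planted genes changed by 2 log2 units. In the real arrays genes varied together, with 49.0% of the variance on 1 component, so these rates may overstate what the test can detect here.

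Only 5 genes differed by 1 log2 unit or more, and none of them separated the groups. Xist, the X-inactivation transcript, differed by -4.46, and the Y-linked genes Uty, Eif2s3y and Kdm5d differed by 2.76, 2.69 and 1.73. AI506816 differed by 1.08, with values from 3.53 to 8.00 over the 6 arrays. The first 4 follow the sex of the embryos. Xist read between 11.60 and 12.25 in the 3 wild-type arrays and 11.68 in knockout replicate 2, but 5.44 and 5.38 in knockout replicates 1 and 3. The mean of the 3 Y-linked genes was 8.20 and 7.86 in those 2 arrays and between 4.32 and 4.48 in the other 4. The groups therefore differed in sex as well as in Tnc, and without knockout replicate 2 these 4 genes were the only ones past an adjusted p of 0.05. A fit with a sex term compares knockout replicate 2 alone with the wild-type arrays. Values given below with a sex term thus compare only arrays without Y-linked signal. They are free of the sex difference, but they rest on that 1 knockout array and decide nothing by themselves.

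**Figure D2:**
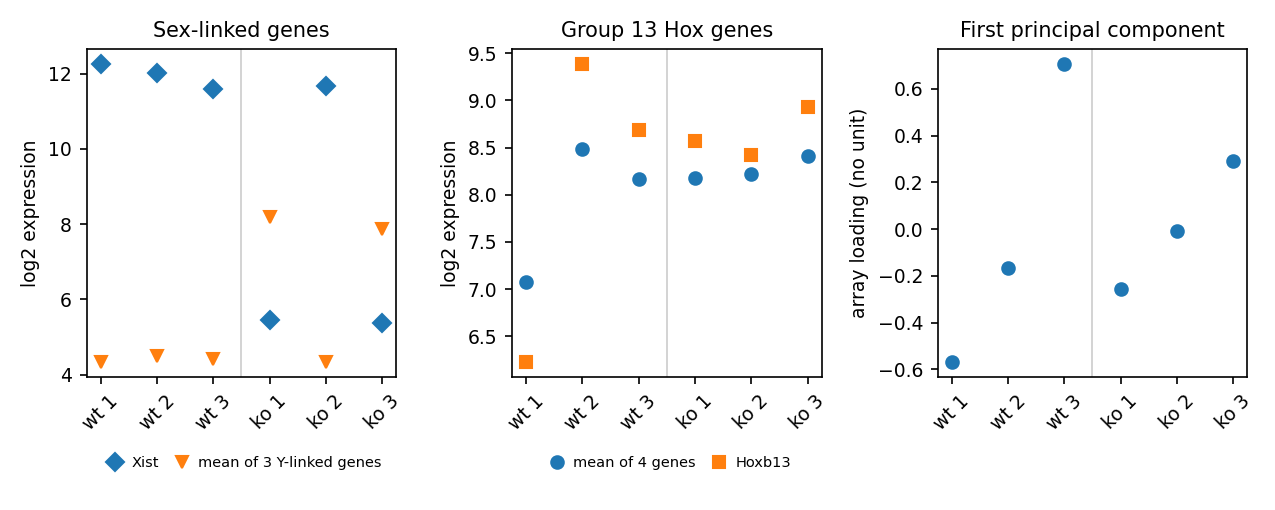
Values of each wild-type (wt) and knockout (ko) array by replicate number: log2 expression of Xist and the mean of 3 Y-linked genes (left), log2 expression of Hoxb13 and the mean of 4 group 13 Hox genes (middle), and the array's loading on the first principal component (right). The Y-linked mean is 8.20 and 7.86 in knockout replicates 1 and 3 and at most 4.48 elsewhere, and Hoxb13 is 6.22 in wild-type replicate 1 and at least 8.42 elsewhere.

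The genes with the smallest p values in each direction, none of them past the test, came in large part from the chromosome that carries Tnc. Among the 10 higher in knockout were Hdhd3 at 0.71, Ugcg, the ceramide glucosyltransferase, at 0.45, Alad, the heme-synthesis enzyme delta-aminolevulinate dehydratase, at 0.40, and the tyrosine phosphatase Ptpn3 at 0.32 log2 units. These 4 lie on chromosome 4 with Tnc. The other 6 lie on other chromosomes. They were 4930505O20Rik at 0.52, the matrix protein vitronectin (Vtn) at 0.47, Ccdc3 at 0.44, Lgi3 at 0.42, the mitochondrial ribosomal protein gene Mrps10 at 0.37 and the sialyltransferase St8sia5 at 0.36. The unadjusted p of these 10 ran from 0.00100 to 0.00362. Among the 10 lower in knockout, Tnc, Tmod1 (-0.35), which caps actin filaments, and Galt (-0.29), the galactose-1-phosphate uridylyltransferase, lie on chromosome 4. The others were Vmn1r58 (-0.53), Fgfr1op2 (-0.44), Gm4787 (-0.33), 2410022M11Rik (-0.33), lumican (Lum, -0.30), Ugt2b38 (-0.27) and Adam29 (-0.26), with unadjusted p from 0.000545 to 0.00554 over the 10. 4930505O20Rik among the higher genes and Vmn1r58, Lum, Gm4787, Adam29 and Ugt2b38 among the lower had means under 6.13 in both groups, the 95th percentile of 1194 olfactory and vomeronasal receptor genes, which serves as a guide to background signal here.

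Of 36 measured genes on a list of chromosome 4 neighbours of Tnc, 20 were higher and 16 lower, with a median log2 change of 0.01 and a camera adjusted p of 0.0790 for the list. The list passed without genes under the 25th percentile of level (median 0.04, adjusted p 0.00701) or under the median level (0.04, 0.00722) and with an intensity trend (0.01, 0.0430), and its median was -0.01 without wild-type replicate 1. Adjusted over the list alone, 3 genes passed (Ugcg, Hdhd3 and Alad), and over all genes tested 0 passed. Hdhd3 was 8.36 ± 0.35 in wild type and 9.07 ± 0.07 in knockout, or 163% of wild type (SD, n = 3 each). Ugcg was 10.61 ± 0.06 against 11.06 ± 0.14, and Alad was 11.46 ± 0.18 against 11.86 ± 0.04 (SD, n = 3 each). No member passed over the list alone without wild-type replicate 2, without knockout replicate 1 or without knockout replicate 2.

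**Figure D3:**
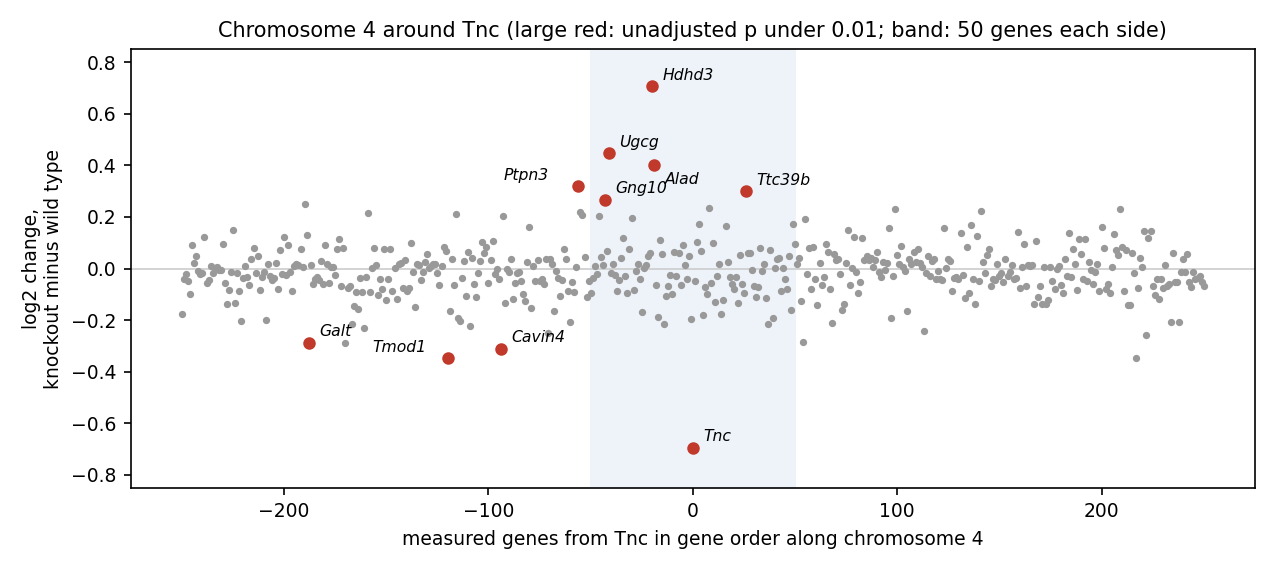
Log2 change, knockout minus wild type (vertical axis), of measured genes on chromosome 4 by their place in gene order from Tnc (horizontal axis, number of measured genes), with genes at an unadjusted p under 0.01 drawn large in red and the 50 genes on each side of Tnc shaded. The shaded band holds Tnc at -0.69 and 5 other red points, all above 0.

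Spinal cord patterning factors, the transcription factors that divide the ventricular zone into domains, did not pass as a list. Of 28 measured members 16 were higher and 12 lower, with a median of 0.04 and an adjusted p of 0.0606. The list passed without wild-type replicate 2 (median 0.08, adjusted p 0.00318), wild-type replicate 3 (0.08, 0.0283) or knockout replicate 1 (0.08, 0.00248), and also without genes under the 25th percentile (0.04, 0.0225) or the median (0.11, 0.00722) of level. Its median was -0.10 without wild-type replicate 1 and -0.02 without knockout replicate 3. Nkx2-2, which marks the p3 domain and later oligodendrocyte precursors, was 7.81 ± 0.13 in wild type and 8.11 ± 0.07 in knockout (SD, n = 3 each), a log2 difference of 0.30 with a confidence interval from 0.10 to 0.51. The floor-plate factor Foxa2 differed by 0.25 and Olig2, the motor neuron and oligodendrocyte progenitor factor, by 0.24, and the groups did not overlap for any of these 3. Nkx6-1 differed by 0.25 and Pax6 by 0.14 with overlapping groups, and without wild-type replicate 1 by only 0.07 and -0.00619. The ventral factors Nkx2-9 and Nkx6-2 differed by 0.05 and -0.03, and Irx3 by 0.21 (0.10 without wild-type replicate 1). Nkx2-9 differed by -0.13 without wild-type replicate 1 and by 0.21 without wild-type replicate 3. Nkx6-2 differed by -0.12 without wild-type replicate 1 and by 0.03 without wild-type replicate 3. Without wild-type replicate 3 the difference of Olig2 was 0.16. Among dorsal factors Atoh1 differed by -0.27, Msx3 by -0.19, Pax7 by -0.05, Pax3 by -0.01 and Gsx1 by 0.06, and no ventral or dorsal part of the list was tested. Without wild-type replicate 2 Atoh1 and Msx3 each differed by only -0.10, and Pax7 and Pax3 by 0.07 and 0.16. The unadjusted p was 0.00948 for Nkx2-2, 0.0195 for Foxa2 and 0.0341 for Olig2, and none passed over all genes or over the list alone.

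Genes tied to the position of ventral white matter astrocytes rose as a set, 5 of 6 being higher, with a median of 0.16 and a camera adjusted p of 0.00750 (adjusted p = 0.366 with an estimated correlation). No member passed singly. Of the 5 higher, Nkx2-2 (0.30), Nkx6-1 (0.25) and Pax6 (0.14) are shared with the patterning list. Fgfr3, an early astrocyte-lineage receptor, was 9.99 ± 0.20 in wild type and 10.16 ± 0.15 in knockout (SD, n = 3 each), and its difference of 0.17 had an interval from -0.10 to 0.45 and was 0.06 without wild-type replicate 1 and 0.10 without knockout replicate 3. Slit1, which marks ventral astrocyte subtypes, differed by 0.04, with an interval from -0.14 to 0.22. Reln differed by -0.07. Part of this list consists of genes the study itself is concerned with, so its direction is not independent evidence. Its median was 0.07 and its adjusted p 0.0629 without wild-type replicate 1, and its call also ended without wild-type replicate 3 (median 0.20, adjusted p 0.0547) and without knockout replicate 3 (median 0.11, adjusted p 0.0678). The call was lost as well with array weights (median 0.09, adjusted p 0.0946), with camera on ranks (adjusted p 0.0512) and without both wild-type end arrays (0.07, 0.173). Without wild-type replicate 2 its median was 0.24.

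The astrocyte lineage list rose as a set, with 19 of 26 members higher, a median of 0.06 and an adjusted p of 0.00750 (adjusted p = 0.366 with an estimated correlation). The water channel Aqp4 differed by 0.26 and Mlc1, a membrane protein of astrocyte endfeet, by 0.17, while the connexin gene Gjb6 differed by -0.33. The glutamate transporters Slc1a3 and Slc1a2 differed by 0.05 and -0.13. Gfap, the intermediate filament of mature astrocytes, read 5.91 ± 0.22 in wild type and 5.99 ± 0.04 in knockout (SD, n = 3 each), below the background guide of 6.13 in both. The call ended without wild-type replicate 3 (median 0.06, adjusted p 0.0941) and without knockout replicate 2 (median 0.05, adjusted p 0.126). It also ended without both wild-type end arrays (median 0.07, adjusted p 0.137). Without wild-type replicate 1 it held at a median of 0.03, and with array weights at 0.08. With a sex term, which leaves 1 knockout array, the median was 0.11.

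The oligodendrocyte lineage list also rose as a set, with 14 of 19 members higher, a median of 0.07 and an adjusted p of 0.000200 (adjusted p = 0.303 with an estimated correlation). Its mean lay higher in each knockout array than in each wild-type array. Chance alone separates 3 arrays from 3 in 10% of cases. Its leading members were Nkx2-2, Olig2 and Olig1 (0.22), which the patterning list shares, followed by Cnp (0.17). The precursor markers Pdgfra and Cspg4 differed by 0.14 (0.01 without wild-type replicate 3) and 0.12, the myelin genes Mbp and Mog by 0.07 and -0.03, and Cldn11 by -0.24. Cldn11 differed by -0.10 without wild-type replicate 2 and by -0.39 without wild-type replicate 3, where Mog differed by 0.08. Without wild-type replicate 3 the call ended at an adjusted p of 0.0941 although the median was 0.13. The call held at medians of 0.12 with a sex term, without both wild-type end arrays and without genes under the median level, and of 0.13 with array weights.

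Radial glia and neural progenitor genes did not pass, with 12 of 20 higher, a median of 0.02 and an adjusted p of 0.251. Prom1, a membrane protein of progenitors, differed by 0.23 and Sox2 by 0.12. Fabp7 was 13.55 ± 0.07 in wild type and 13.55 ± 0.02 in knockout (SD, n = 3 each), and the interval of its difference ran from -0.17 to 0.17. Sox9, Nfia and Nes differed by 0.02, -0.01 and -0.06. The list passed without wild-type replicate 2 (median 0.06, adjusted p 0.0332) or knockout replicate 1 (0.07, 0.0110), and its median was 0.08 with a sex term. However, its median was -0.01 without wild-type replicate 1, -0.00417 without knockout replicate 2 and -0.00227 without knockout replicate 3. The proliferation lists did not pass either. S phase genes had 14 of 21 members higher (median 0.02, adjusted p 0.191, with Rrm2 at 0.16 and Mcm3 at 0.16), and G2 and M phase genes had 18 of 23 higher (median 0.04, adjusted p 0.191, with Bub1b at 0.21 and Kif20a at 0.16, or 0.08 and -0.01 without wild-type replicate 1). Both passed without wild-type replicate 2, S phase at 0.07 (adjusted p 0.00575) and G2 and M phase at 0.15 (adjusted p 6.63e-08). The G2 and M phase median was -0.06 without wild-type replicate 1 and -0.01 without knockout replicate 3, so its direction depends on single arrays. With array weights it passed in the lower direction (median -0.12, adjusted p 0.00627), as it did without both wild-type end arrays (-0.18, 1.30e-06).

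Spinal cord neuron genes rose as a set, with 13 of 19 higher, a median of 0.06 and an adjusted p of 0.0140 (adjusted p = 0.580 with an estimated correlation). Their leading members were Gad1, which makes GABA, at 0.14 and Elavl4 at 0.11, while Dcx and Rbfox3 differed by 0.01 and -0.00. Motor neuron genes rose as a set, with 14 of 16 higher, a median of 0.08 and an adjusted p of 0.0140 (adjusted p = 0.839 with an estimated correlation). Mmp9 differed by 0.19, Lhx3 by 0.19 (0.02 without wild-type replicate 1), Chat by 0.06 (-0.02 without wild-type replicate 1) and Aldh1a2 by -0.12. The motor neuron call ended without wild-type replicate 1, where the median was -0.00299 and the adjusted p 0.589, and also without knockout replicate 1 (median 0.09, adjusted p 0.106) or 2 (0.06, 0.126) and with renewed quantile normalization (0.09, 0.0645). The motor neuron median was 0.15 without wild-type replicate 3 and 0.12 with a sex term. The neuron call ended without wild-type replicate 2 (median 0.04, adjusted p 0.0851) or 3 (0.05, 0.408) and without knockout replicate 1 (0.04, 0.0772) or 2 (0.03, 0.148). It depended on normalization too, ending with renewed quantile normalization (0.06, 0.145) and with cyclic loess (0.06, 0.0754), and it ended without both wild-type end arrays (0.05, 0.0518). Interneuron identity factors did not pass, with 17 of 26 higher, a median of 0.07 and an adjusted p of 0.191. Gata3, a factor of V2b interneurons, differed by 0.32 and the dorsal factor Lmx1b by -0.18. That list passed without wild-type replicate 2 (median 0.05, adjusted p 0.0452) or 3 (0.18, 0.0335) while its median was -0.04 without wild-type replicate 1 and 0.04 without knockout replicate 2.

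**Figure D4:**
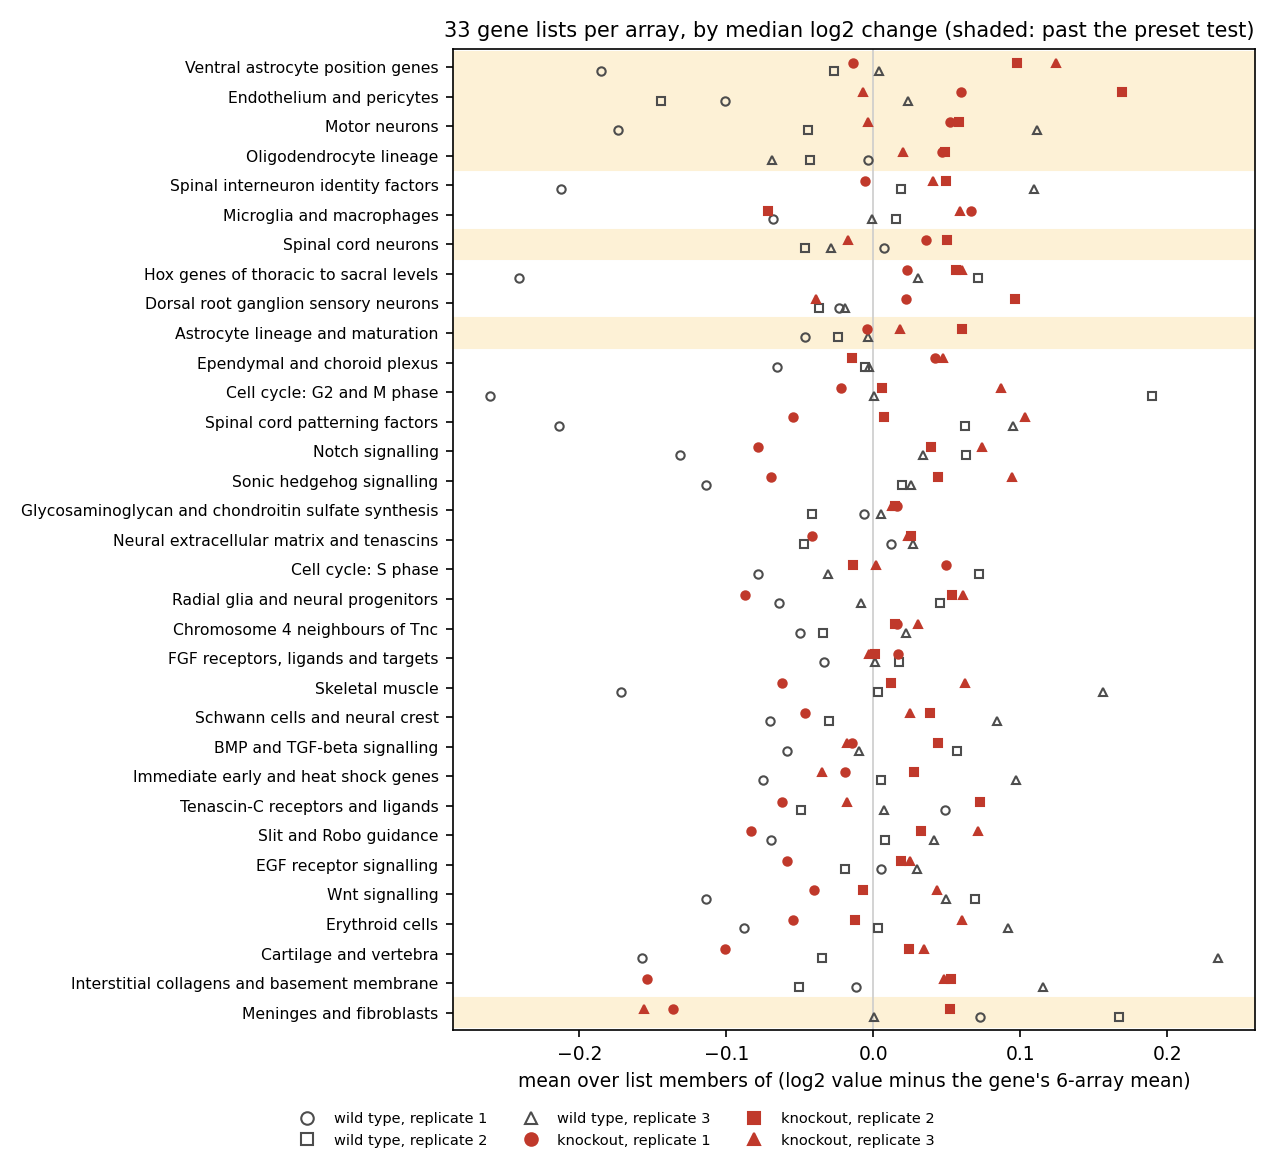
Mean over the members of each of 33 gene lists of the log2 value minus the gene's mean over 6 arrays (horizontal axis, log2 units), for each wild-type (open grey) and knockout (filled red) array, ordered by the median log2 change, with lists past the preset-correlation test shaded. Of the 7 shaded lists, only the oligodendrocyte lineage list has all 3 knockout arrays on one side of all 3 wild-type arrays.

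The clearest shift among cell types other than the neural ones was in endothelium and pericytes. Of 16 measured markers 15 were higher in knockout, with a median of 0.15 and an adjusted p of 3.21e-09 (adjusted p = 0.366 with an estimated correlation). The junction protein VE-cadherin (Cdh5) differed by 0.26, endoglin (Eng) by 0.25, the receptor Tie1 by 0.23, Pecam1 by 0.20 and Esam by 0.18, each with knockout arrays wholly above wild type. The list passed at each array left out. Its median fell to 0.10 without wild-type replicate 2 or knockout replicate 2 and rose to 0.21 without wild-type replicate 3 or knockout replicate 3. It was also larger with array weights (0.26), with a sex term (0.29) and without both wild-type end arrays (0.22). The pericyte marker Pdgfrb differed by 0.09 and Egfl7 by -0.08. Meningeal and fibroblast genes fell as a set, 13 of 16 being lower, with a median of -0.16 and an adjusted p of 0.00247 (adjusted p = 0.370 with an estimated correlation). Postn differed by -0.53, Slc6a13 by -0.46, Ptgds by -0.38 and Lum by -0.30, while decorin (Dcn) was higher by 0.38. Postn differed by 0.02 without wild-type replicate 1, and without wild-type replicate 2 Ptgds differed by -0.02 and Slc6a13 by -0.18, so these rest on single arrays. The meningeal call ended without knockout replicate 1 (median -0.14, adjusted p 0.106), without knockout replicate 3 (-0.13, 0.0678) and without genes under the median level (-0.12, 0.364). With a sex term, which leaves 1 knockout array, the meningeal median was -0.02.

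None of the signalling lists passed with all 6 arrays. Sonic hedgehog genes had 9 of 15 members higher (median 0.03, adjusted p 0.217), led by the heparan sulfate endosulfatases Sulf1 at 0.49 and Sulf2 at 0.17. Notch genes had 12 of 19 higher (median 0.03, adjusted p 0.251), with Jag2 at 0.18 and Hes6 at -0.20. FGF receptors, ligands and targets had 12 of 22 higher (median 0.01, adjusted p 0.506). Fgf2 itself was 6.40 ± 0.07 in wild type and 6.56 ± 0.05 in knockout (SD, n = 3 each) without overlap, and Fgf15 differed by -0.26. EGF receptor signalling had 6 of 12 higher (median -0.02, adjusted p 0.839), with Egfr at -0.05, Hbegf at 0.16 and Erbb4 at -0.21. BMP and TGF-beta signalling had 12 of 26 higher (median -0.01, adjusted p 0.546), with Tgfb2 at 0.14 and Id1 at -0.13. Wnt signalling had 11 of 25 higher (median -0.02, adjusted p 0.880), with Sfrp2 at 0.24 (0.07 without wild-type replicate 1) and Dkk3 at 0.12. Slit and Robo guidance had 4 of 9 higher (median -0.01, adjusted p 0.839), with Slit3 at 0.26 (0.04 without wild-type replicate 1) and Srgap2 at -0.12. With 1 array left out, the Notch list passed without wild-type replicate 2 (median 0.08, adjusted p 0.0169) or knockout replicate 1 (0.07, 0.0172), the hedgehog list without knockout replicate 1 (0.09, 0.0284) and the BMP list without wild-type replicate 2 (0.04, 0.0452). Without wild-type replicate 1 the medians of these 3 lists were -0.05, -0.04 and -0.01.

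Matrix genes other than Tnc did not pass as lists. Neural extracellular matrix and tenascin genes had 17 of 26 higher (median 0.02, adjusted p 0.392), with the proteoglycan brevican (Bcan) at 0.18 and the hyaluronan synthase Has2 at -0.25. Receptors and ligands of tenascin-C had 10 of 21 higher (median -0.01, adjusted p 0.920), with Ptprb at 0.19 and Tlr4 at -0.18. Interstitial collagens and basement membrane genes had 7 of 21 higher (median -0.04, adjusted p 0.251), with Col1a2 at -0.17 and Col6a3 at -0.15. Chondroitin sulfate and other glycosaminoglycan synthesis genes had 15 of 23 higher (median 0.03, adjusted p 0.0798), with Dse at 0.17 and Chpf at 0.13, and this list's mean was also higher in every knockout array. For the EGF, BMP, Wnt, Slit and tenascin-C receptor lists the median was below 0 while the test's direction was up. The collagen list passed without wild-type replicate 2 (median -0.08, adjusted p 0.0374) or knockout replicate 2 (-0.08, 0.0306), but its median was 0.03 without wild-type replicate 3 and 0.02 without knockout replicate 1. The glycosaminoglycan list passed without wild-type replicate 1 (0.04, 0.0456) and had a median of -0.00144 without wild-type replicate 2. The list of tenascin-C receptors had a median of 0.05 with a sex term.

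Markers of other tissues that a dissection can carry did not pass with all 6 arrays. Dorsal root ganglion sensory neurons had 10 of 14 higher (median 0.06, adjusted p 0.117, with Scn10a at 0.29 and Trpv1 at 0.13), and Schwann cells and neural crest had 6 of 12 higher (median -0.00, adjusted p 0.719, with Ngfr at 0.20 and Mal at -0.18). Microglia and macrophages had 10 of 14 higher (median 0.07, adjusted p 0.216, with Aif1 at -0.19 and Laptm5 at 0.13). Erythroid cells had 4 of 10 higher (median -0.03, adjusted p 0.839, with Klf1 at -0.16 and Hbb-bh1 at -0.14). Skeletal muscle had 10 of 20 higher (median 0.00, adjusted p 0.719, with Acta1 at 0.15 and Myf5 at -0.19). Cartilage and vertebra had 6 of 17 higher (median -0.04, adjusted p 0.40, with Snorc at -0.22 and Cnmd at -0.09). Ependymal and choroid plexus genes had 9 of 14 higher (median 0.04, adjusted p 0.0998, with Enkur at 0.27 and Dynlrb2 at 0.18). Of these genes Scn10a, Trpv1, Aif1, Hbb-bh1, Myf5, Enkur and Dynlrb2, like Tlr4 above, had means under the background guide of 6.13 in both groups. With 1 array left out, cartilage passed without wild-type replicate 1 (median -0.09, adjusted p 0.0195) but had medians of 0.11 and 0.05 without wild-type replicate 3 and knockout replicate 1. Likewise passing were sensory neurons without knockout replicate 3 (0.07, 0.0204), and microglia (0.11, 0.0198) and ependyma (0.06, 0.0488) without knockout replicate 2. The sensory neuron median was 0.14 with a sex term. Microglia also passed without genes under the 25th percentile of level (0.07, 0.0177). Medians were near 0 for sensory neurons without knockout replicate 2 (0.01), microglia without knockout replicate 1 (0.01) and ependyma without wild-type replicate 1 (0.01).

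Hox genes of thoracic to sacral levels, which track position along the body axis, had 14 of 20 higher (median 0.06, adjusted p 0.0673), with Hoxd13 at 0.30 and Hoxb7 at -0.13. The list passed without wild-type replicate 2 (median 0.04, adjusted p 0.0152) and with an intensity trend (0.06, 0.0448), and its median was 0.10 with a sex term. Without wild-type replicate 1 its median was 0.02, and without knockout replicate 2 it was 0.03. Wild-type replicate 1 stood apart in the most caudal group. Its mean over Hoxa13, Hoxb13, Hoxc13 and Hoxd13 was 7.07, against 8.17 to 8.48 in the other 5 arrays, and its Hoxb13 was 6.22 against 8.42 to 9.38. Its mean was also the lowest of the 6 arrays for many lists, among them the patterning, ventral astrocyte position, motor neuron and interneuron lists. Immediate early and heat shock genes had 9 of 19 higher (median -0.01, adjusted p 0.826, with Gadd45b at -0.17 and Atf3 at -0.17). Sex-linked genes had 4 of 7 higher (median 0.06, adjusted p 0.217), and passed without knockout replicate 2 (median 0.06, adjusted p 8.79e-05). Only 2 mitochondrially encoded genes were measured, COX2 at -0.04 and ND3 at 0.00, too few for a test. Beyond the genes with a single symbol, 9 transcript clusters that each list 6 or 7 symbols fell past an adjusted p of 0.05, from between 8.35 and 9.37 on the wild-type arrays to between 6.54 and 7.01 on the knockout arrays.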

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

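The tests of sex for the genes near Tnc and for the endothelium list, and the splits for both and for the number of lists, were written down before their values were seen. The tests of chance clustering, flanking DNA and attached tissue, the splits for the 2 gene counts, and all tests on the 9 transcript clusters below were chosen only after the result was seen. The comparison of the true grouping with the other ways to divide 6 arrays into 3 and 3 has 10 splits, so its share can never be under 0.05.

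A set of 9 transcript clusters, each of which lists 6 or 7 symbols and so names no single gene, was much lower in every knockout array. The log2 changes were -2.30 (10504121), -2.45 (10504123), -2.45 (10504125), -2.02 (10504139), -2.39 (10504148), -2.50 (10504169), -2.09 (10504172), -2.40 (10504178) and -2.46 (10512327), or 17.7% to 24.6% of wild type. Adjusted p in limma ran from 0.00357 to 0.0173 over the clusters without exactly 1 symbol. They share 6 of 7 listed symbols, 2 have identical values and the lowest correlation between any 2 is 0.995, so they count as 1 observation. Between 6 and 9 of them stayed past the threshold when any 1 array was left out.

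Sex was tested for these clusters through knockout replicate 2, the 1 knockout array without Y-linked signal. It showed a median of 100.6% of the change, from 99.1% to 108%, where a sex effect would leave it at the wild-type level, but 1 array decides nothing and sex stays open. The symbols found in the gene table all lie on chromosome 4, 4 of them within 5 measured genes of Galt. Chromosome 4 DNA carried along with the targeted allele may be a source, and this stays open. Of other clusters with several symbols on 1 chromosome, 2 of 56 on chromosome 4 had an unadjusted p under 0.01 against 0 of 870 elsewhere (Fisher's exact p = 0.00360), but those 2 list the same symbols, and with equal symbols counted once it was 1 of 35 against 0 of 582 (Fisher's exact p = 0.0567). Of the 10 splits, 1 gave as many clusters past the threshold, the real one with 9, and the highest other gave 1. The labels give 1 strain for both groups, and whether the knockouts carry other DNA near Tnc is not given in the sources used here, so a direct effect of losing tenascin-C and an effect of linked DNA cannot be told apart.

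Genes at an unadjusted p under 0.01 gathered near Tnc on chromosome 4, where 5 of the 100 nearest measured genes (Gng10, Ugcg, Hdhd3, Alad and Ttc39b, all higher) reached it. The count was 6, 2 and 4 without wild-type replicates 1, 2 and 3 and 2, 3 and 2 without knockout replicates 1, 2 and 3. The gathering is wider than the closest genes, with 4% of the 50 within 25 genes of Tnc, 6% of those 26 to 50 away and 2% of those 51 to 100 away. The densest window, centred on Musk 50 genes away, held 7, Tnc among them, and chromosome 4 held 11 of all 43. The share was 0.187% among all other genes (Fisher's exact p = 2.15e-06), which restates the gathering and does not bear on its source, so DNA flanking the targeted allele stays open. In the fit of all 6 arrays chance clustering is argued against, as 0% of 16791 windows of the same size on other chromosomes held as many. The highest count there was 2. These windows were moved by 1 gene at a time and overlap, so far fewer of them are independent. They were not counted again with 1 array left out, where the count near Tnc fell as low as 2. Knockout replicate 2 showed a median of 89.2% of these changes, and as that is 1 array, sex stays open. As many genes near Tnc came from 2 of the 10 splits, the real one with 5 and a highest other of 6. That other split had 1123 genes at an unadjusted p under 0.01 over all genes, against 43 in the real one. The 2 counts near Tnc are thus not at like base rates, and the 1123 point to a structure of the samples.

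The endothelium and pericyte list stood higher in knockout by a median of 0.15. With a sex term, which leaves knockout replicate 2 to carry the comparison, its median was 0.29 with 15 of 16 members higher, but that rests on 1 array, so sex stays open. More attached tissue would raise meningeal genes alike, but their median was -0.16 (standard error 0.07), and endothelium stood above them by 0.30 (0.08). With the sex term the meningeal median was -0.02 and endothelium stood 0.31 above, from 1 knockout array. These standard errors treat genes of the same arrays as independent, which they are not. Sensory ganglion genes, another attached tissue, had a median of 0.06, and of 0.14 with the sex term. Spinal cord neuron genes had a median of 0.06 as well. Those of Schwann cells, skeletal muscle and cartilage, also attached tissues, had medians of -0.00, 0.00 and -0.04. The medians of these last lists changed sign when some single array was left out. Among attached tissues only ganglion genes stood higher, and as the lists do not go alike, attached tissue stays open. Of the 10 splits 2 shifted the endothelium list as far, the real one at 0.15 and a highest other at 0.18. A larger share of vessels in the knockout cord and more transcript per vessel cannot be told apart in whole tissue.

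The other counts were set against the same 10 splits. For genes past the adjusted threshold the real count was 0 and the highest other 1, so all 10 splits reach it by construction and the comparison says nothing about chance. For genes at an unadjusted p under 0.01, 8 splits gave at least the real 43, and the highest other of 1123 points to a structure of the samples unrelated to Tnc. For gene lists 4 splits gave at least the real 7, with a highest other of 11.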

How the results depend on the processing

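The sex term, cyclic loess and the removal of both wild-type end arrays were chosen only after the result was seen. Genes past the threshold numbered 0 under most settings, 9 with all transcript clusters of the table, 43 at an unadjusted p under 0.01, and 0 to 4 when 1 array was left out, the 4 being the sex genes without knockout replicate 2. Lists past the test numbered 0 with an estimated correlation and 0 by fry, and 5 (without wild-type replicate 3) to 15 (without wild-type replicate 2) when 1 array was left out. Among the 7 lists past the test, motor neurons alone reversed with 1 array left out, without wild-type replicate 1, at -0.00299, and reached 0.15 without wild-type replicate 3. A sex term leaves knockout replicate 2 alone against the wild type, so no count of lists is given for it. The change of Tnc ran from -0.84 to -0.49.

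With the replicate block 0 genes and 9 lists passed, interneuron (adjusted p 0.0436) and Hox genes (0.0279) among them, and Tnc was at -0.69. After each gene's group mean was subtracted, correlations between samples of the same number were 0.345, -0.0746 and 0.449. By these correlations, samples of numbers 1 and 3 matched their own number in the other group best. Those of number 2 matched number 1, so there is a hint of pairing for 2 of the 3 numbers only.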

Other observations

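Some genes varied widely between arrays without regard to Tnc. AI506816 read 5.59, 7.73 and 3.53 in wild type and 7.87, 8.00 and 4.22 in knockout, and Wdfy1, an endosomal adaptor, was low only in replicate 3 of each group (7.71 and 7.83, against 9.06 to 9.77). Myo7a, an unconventional myosin, was 7.02 in wild-type replicate 3 and 6.70 and 6.98 in knockout replicates 1 and 3, against 8.38 to 8.53 in the others. Gpr137b-ps was 7.73 and 8.03 in wild-type replicate 2 and knockout replicate 3 and 8.95 to 9.24 elsewhere. Alb, the liver albumin gene, was highest in knockout replicate 1 at 7.28, and Postn, a matrix protein of connective tissue, in wild-type replicate 1 at 7.90. The small nucleolar RNAs Snora73a and Snora73b were 8.43 and 8.49 in knockout replicate 2, against 9.63 or more elsewhere.

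The first principal component held 49.0% of the variance and set wild-type replicates 1 and 3 at its ends (-0.57 and 0.70), with the 3 knockout arrays between them. It kept 42.6% after cyclic loess. Wild-type arrays correlated with each other from 0.993 to 0.997 and knockout arrays at 0.997. Tests in this part were chosen only after the result was seen.

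What to look at next follows from these values. The genotype at polymorphic sites on chromosome 4 in the same embryos would show whether linked DNA is present. If it is, these embryos alone cannot separate its effect from loss of tenascin-C. Counts of vessels and of Nkx2-2 cells in cords of matched sex and axial level would test the endothelial median of 0.15 and the Nkx2-2 difference of 0.30, neither of which rests on a gene past the adjusted threshold.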
